A study of Drosophila melanogaster with 236 samples.

How the data were processed

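Gene expression was measured in pools of 30 whole third-instar larvae of Drosophila melanogaster on 236 single-colour NimbleGen arrays of 2 designs. Per the labels' protocols, first instars were placed at 50 per vial on a diet, were fed for 3 days, were fasted for 6 hours and were frozen. The labels give a line (21), a diet (C, N, 4 or F), a biological replicate number, a slide and a position for each array, and they do not say what the diet letters or the line prefixes M and NC2 stand for. Arrays with the same line, diet and replicate number were taken as the same pool, per the series design text, which gave 197 pools, of which 33 were on 2 arrays and 3 on 3 arrays. The labels also give 6 trait values per line and diet for 20 lines (not for line M051), and a value named ai for 14 lines.

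The deposited values are log2 signals per transcript, summarised with RMA from 8 probes each per the submitters' processing notes, whose software version is not given in the sources used here. The medians of single arrays ranged from 6.97 to 13.01 (log2), so the deposited table was not normalized between arrays. Before the data were examined, the plan took the values as deposited as the main choice, with quantile normalization as an alternative. After the array medians had been seen, the choices were swapped, and the main values are the deposited ones after quantile normalization with limma 3.58.1 in R 4.3.3. The 15595 transcripts were named from a table of locus tags and symbols, and 14919 had a symbol. Where several transcripts named 1 gene, the transcript with the highest mean was kept, which left 13202 genes or unnamed transcripts, 12576 of them with a symbol. No filter on dim signals was applied. Coordinates are those of the array annotation DMr43.

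A limma model with 1 coefficient per line and diet (84 cells) plus slide (23 slides) gave cell means, with arrays of 1 pool as a random block (estimated correlation 0.446). Diet and line effects were tested with limma's moderated statistics in a line plus diet model of the 84 cell means, so that the 21 lines are the replicates of a diet effect and the error is the line-by-diet deviation. As the labels name no reference diet, each diet was set against the mean of the other 3, and all pairs of diets were compared. The line-by-diet interaction was tested over 60 contrasts of the array-level model, against the spread between pools. Lines named M (13) were compared with lines named NC2 (8) on line means. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and the threshold was an adjusted p of 0.05.

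Trait values were tested by two-sided permutation tests with 100000 shuffles of diets within lines or of lines within diets, or with sign flips for pairs of diets, in Python 3.11.15 with NumPy 2.4.6 and SciPy 1.17.1. As each line and diet has 1 trait value, no interaction was tested for traits. Line-mean expression was regressed on each standardized trait with limma between lines, and cell means were regressed on traits with line and diet as terms.

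Before the data were examined, 29 gene lists and the rule for naming genes were fixed. For each diet the rule names the 3 largest rises and the 3 largest falls among genes past the threshold that had the same sign in at least 18 of the 21 lines. It also names the 20 highest F values for line and for interaction, and the 3 smallest p-values per trait. Members of a list may be named as examples by smallest p. The lists were tested with camera in limma at a preset inter-gene correlation of 0.01, and with an estimated correlation as the alternative. After the data had been seen, a permutation test of each list's mean was added, with 100000 shuffles of the diets within lines and adjustment over 29 lists and 4 diets. Lists among genes called for line were tested by Fisher's exact test.

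The alternatives fixed before the data were examined were the values as deposited, median centring, no slide term, pools as replicates, 1 array per pool, array weights, each array design alone, the mean of all transcripts of a gene, no dim genes, the replicate number as a block, ranked traits and each replicate number or line left out. Limma's default array weights did not converge, and its gene-by-gene method was then used in its place. Fits without the arrays that matched another line, without arrays of low correlation, and with a larval stage score as a covariate were added after the data had been seen, as were list means under other scalings. The fits were tested on simulated data with known changes: 84 of 100 genes with a change of 0.5 log2 on diet C, 83 of 100 with an interaction of that SD and 84 of 100 with a slope on development time were recovered, with 15, 4 and 13 false calls among 12589 unchanged genes. The simulated errors were independent between genes, so false calls that arise in many genes together could not appear. Shuffles of the diets in the real data gave up to 1 call on diet C and 1367 on diet N.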

Results

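The data describe how the transcriptome of third-instar larvae differs between 21 lines raised on 4 diets, which the series title puts as a question of genotype-by-diet interaction. The 236 arrays comprised 58 on diet C, 55 on diet N, 61 on diet 4 and 62 on diet F, from 50, 48, 51 and 48 pools of larvae. Of the 84 combinations of line and diet, 4 had 1 pool, 47 had 2 and 33 had 3. The number of arrays limits the precision of every value. Within 1 line and diet the median residual SD of a gene was 0.50 log2, which holds the spread between pools and that between arrays of 1 pool. Arrays had a median correlation with the others of 0.933 at the middle of their range and 0.782 at the lowest.

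Diet C set larvae apart from larvae of the same line on the other diets. The largest falls were those of alpha-Est8, which encodes a carboxylesterase, the cytochrome P450 gene Cyp4e3, and Acsx1R, a gene of the acyl-CoA synthetase family. The largest rises were those of Eig71Ea, an ecdysone-induced gene of the late salivary gland, Sgs5bis, a gene of the salivary glue, and CtsL3, which encodes a cathepsin-like protease. In limma 427 of 13202 genes differed on diet C from the mean of the other 3 diets, of which 168 were higher and 259 lower.

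alpha-Est8 (3R, 3335065 to 3341391) fell by 1.04 log2 ± 0.14 on diet C, with adjusted p = 5.26e-06 and a fall in 20 lines. Its mean was 10.00 on C, 10.99 on N, 10.81 on 4 and 11.30 on F. Unless stated otherwise, ± beside a gene's diet difference is limma's moderated SE, from the residuals of all 4 diets. It is not the SE of the 21 line differences. Cyp4e3 (2L, 9748012 to 9750020) fell by 1.11 ± 0.20 log2 (adjusted p = 0.000472) in 19 lines. Acsx1R (3R, 15601195 to 15603002) fell by 1.02 ± 0.21 log2 (adjusted p = 0.00243) in 18 lines. Eig71Ea (3L, 15614379 to 15614914) rose by 1.05 ± 0.30 log2 (adjusted p = 0.0318), and its means were 10.24 on C, 8.90 on N, 9.18 on 4 and 9.49 on F. Sgs5bis rose by 1.00 ± 0.25 log2 (adjusted p = 0.0121) in 19 lines and CtsL3 by 1.00 ± 0.23 log2 (adjusted p = 0.00772) in 18. The rise of Sgs5bis was largest in line M092 (5.01 log2), and the next largest was 1.82 in M051. Line M051, whose only array on diet C had a median correlation of 0.842 with the others, gave the largest fall of all lines in Acsx1R (-6.05 log2), Cyp4e3 (-5.41) and alpha-Est8 (-3.85). Among genes chosen after their values were seen, Est-Q, a carboxylesterase gene, fell by 0.93 ± 0.14 log2 (adjusted p = 4.81e-05), CROT, which encodes a carnitine octanoyltransferase of peroxisomes, by 0.43 ± 0.069 (adjusted p = 8.99e-05) and Seipin, a gene of lipid droplet formation, by 0.63 ± 0.10 (adjusted p = 8.09e-05). The count on diet C was 272 without line M019, 263 without M051, 212 without M052, 250 without M073, 228 without NC2 047 and 280 without NC2 081 genes. It was 14, with 0 genes higher, with the values as deposited, 0 without replicate 1 and without replicate 3, 54 without replicate 2, 117 with array weights, 183 (56 higher) with median centring, 239 (50 higher) with no slide term, 67 with design 080306 alone, 0 with design 090901 alone, and 61 with a score of salivary glue genes as a covariate, which was chosen after the data had been seen.

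**Figure D1:**
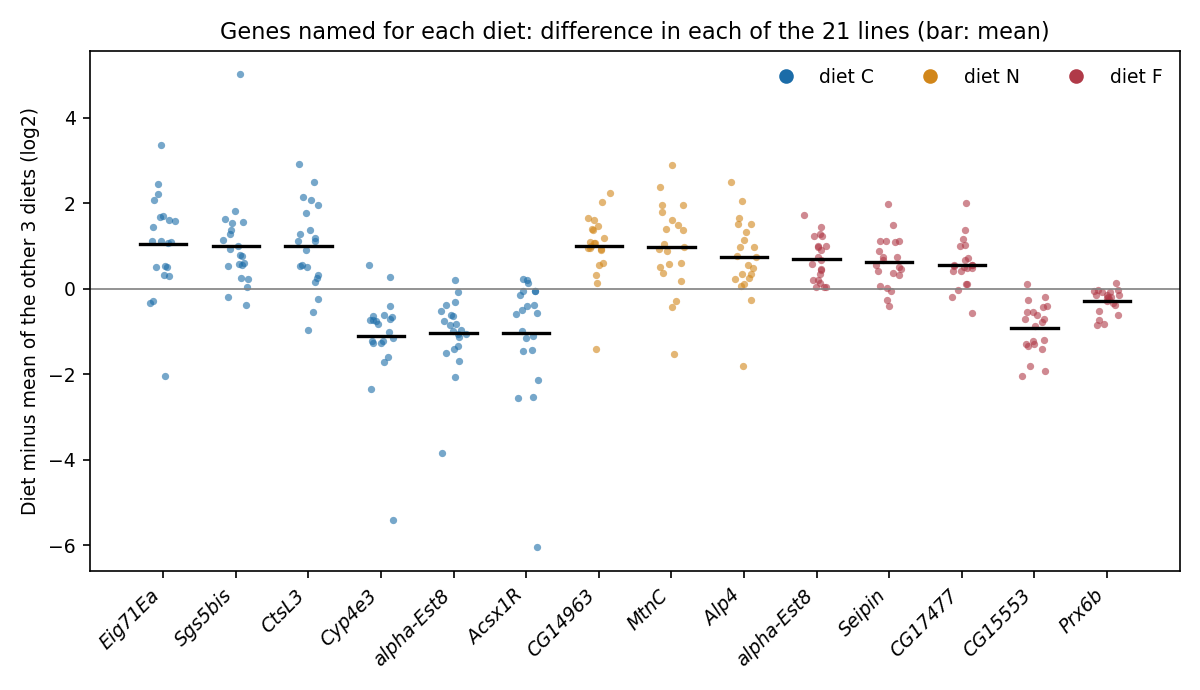
Difference of each named gene between 1 diet and the mean of the other 3 (log2, vertical axis) in each of the 21 lines (points), with the mean over lines (bars). Acsx1R on diet C had its lowest point at -6.05 in line M051, and alpha-Est8 on diet F was above 0 in all 21 lines.

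In a permutation test of list means, 5 lists of lipid and sugar metabolism were lower on diet C, and the list of genes that make the moulting hormone ecdysone was higher. None of these 6 lists passed camera with an estimated correlation (adjusted p = 0.0634 with an estimated correlation for each of the lipid lists, 0.319 for glycolysis, 0.0982 for trehalose and glycogen, 0.419 for pentose phosphate and sugar response and 0.074 for ecdysone synthesis). Of these lists, that of lipolysis and fatty acid oxidation had the largest fall of its mean, with Abcd3, the peroxisomal importer of fatty acids, and Acox57D-d and Acox57D-p, the acyl-CoA oxidases that begin peroxisomal oxidation. Desat1, which introduces the first double bond into fatty acids, and Agpat4, an acyltransferase of glycerolipid synthesis, fell in the synthesis list. The enzymes dib and sad, which make late steps of ecdysone synthesis, rose.

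In the list of lipolysis and fatty acid oxidation 5 of 19 members fell over all genes and 12 fell when adjusted over the list alone, and none rose. Abcd3 fell by 0.31 ± 0.046 log2 (adjusted p = 4.81e-05) and Acox57D-d by 0.57 ± 0.12 (adjusted p = 0.0034). The list's mean fell by 0.21 log2, in 17 of 21 lines (permutation adjusted p = 0.000773). In fatty acid and triglyceride synthesis 3 of 18 members fell over all genes and 7 adjusted over the list alone, and the mean fell by 0.18 log2 in 19 lines (permutation adjusted p = 0.000773). Desat1 fell by 0.20 ± 0.047 log2 (adjusted p = 0.00788), Agpat4 by 0.89 ± 0.21 (adjusted p = 0.00958) and Men, the NADPH-producing malic enzyme, by 0.33 ± 0.084 (adjusted p = 0.0172). Glycolysis, trehalose and glycogen metabolism, and pentose phosphate and sugar-response genes had 0 members past the threshold over all genes in limma, with 7, 5 and 3 members that fell when adjusted over the list alone. The means of these lists fell by 0.15 log2 in 15 lines (permutation adjusted p = 0.0178), by 0.10 in 15 lines (0.00377) and by 0.11 in 14 lines (0.00951), with Ldh at -0.30 log2, Tps1 at -0.15 and sug at -0.57 as examples, and none of these 3 lists passed with each array centred on its median. In ecdysone synthesis 2 of 6 members rose over all genes and 3 adjusted over the list alone, dib by 0.45 ± 0.099 log2 (adjusted p = 0.00571) and sad by 0.43 ± 0.11 (adjusted p = 0.0204), and the mean rose by 0.24 log2 in 20 lines (permutation adjusted p = 0.000773).

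Among the targets of ecdysone, 5 of 19 members of the ecdysone response list rose on diet C over all genes, and 6 rose and 2 fell adjusted over the list alone, the rises with ImpE3 by 0.56 ± 0.13 log2 (adjusted p = 0.011) and ImpE2 by 0.75 ± 0.22 (adjusted p = 0.0396). Their mean did not pass the permutation test (adjusted p = 0.0962), nor did that of the salivary glue list (adjusted p = 0.0758), which does not include Sgs5bis and of which Eig71Ea rose over all genes, while ng1 fell by 0.23 ± 0.067 log2 (adjusted p = 0.0455) and ng3 by 0.23 ± 0.061 (adjusted p = 0.023), with 7 rises and 2 falls among 21 when adjusted over the list alone. Camera at its preset correlation called 36 of the combinations of list and diet, among them lipolysis and fatty acid oxidation (adjusted p = 2.22e-11), fatty acid and triglyceride synthesis (2.83e-06), glycolysis (1.44e-05), trehalose and glycogen (0.000327) and ecdysone synthesis (0.0012) on diet C, but not pentose phosphate and sugar response (adjusted p = 0.074), and 0 held with an estimated correlation. At its preset correlation it also called markers of other tissues lower on diet C, those of muscle (adjusted p = 0.00518; 0.0962 by permutation) and of neurons (0.0357; 0.349 by permutation). Lower there too were oxidative phosphorylation (adjusted p = 3.18e-06), xenobiotic P450s (1.26e-05), digestive proteases (0.00183), lipases (0.0107), cuticle proteins (0.0215) and glutathione transferases (0.0241), and higher were ecdysone response (0.0172) and salivary glue genes (0.0275). The permutation test left 6 lists, all on diet C, of which 3 (ecdysone synthesis, fatty acid and triglyceride synthesis, lipolysis and fatty acid oxidation) passed with each array centred on its median and 0 passed with the values as deposited, where all 6 kept their sign. In 2 fits chosen after the data had been seen all 6 passed. Without the arrays matching another line the test gave 6 calls, and without arrays of low correlation, in 20 lines, it gave 10.

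**Figure D2:**
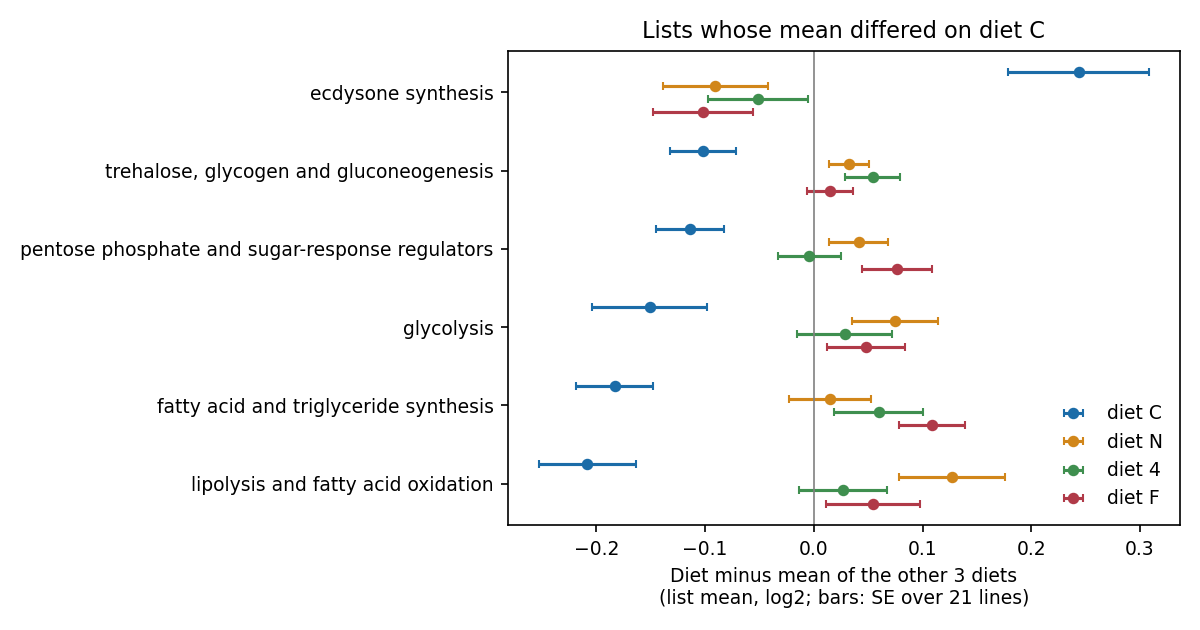
Mean over the genes of a list in 1 diet minus the other 3 diets (log2, horizontal axis), as mean and SE over 21 lines, for the 6 lists that differed on diet C. On diet C ecdysone synthesis was at 0.24 and lipolysis and fatty acid oxidation at -0.21.

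Few genes marked diet N. MtnC and MtnB, which encode metallothioneins that bind copper and other metals, were higher there, and Ctr1B, which encodes a copper importer, was lower. CG14963 and the alkaline phosphatase gene Alp4 were higher too. In limma 12 genes differed on diet N, 9 higher and 3 lower. Of these, 6 were also called on diet C, all 6 with the opposite sign. The mean of the other diets includes diet C, so a change on C adds to the difference on N for such genes.

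CG14963 (3L, 3155288 to 3156073) rose by 1.01 ± 0.14 log2 (moderated SE, adjusted p = 4.39e-06) in 20 lines. Its means were 12.83 on N against 11.74 on C, 11.71 on 4 and 12.01 on F. MtnC (3R, 16186068 to 16186258) rose by 0.99 ± 0.18 log2 (adjusted p = 0.00374) in 18 lines, with means of 10.28 on N, 9.57 on C, 9.06 on 4 and 9.26 on F. Alp4 rose by 0.74 ± 0.16 log2 (adjusted p = 0.0389) in 19 lines. Line NC2 038 went the other way in all of these (-1.41, -1.51 and -1.81 log2). MtnB and Ctr1B were singled out after their values were seen. MtnB rose by 0.87 ± 0.16 log2 (adjusted p = 0.00438) in 16 lines and Ctr1B fell by 0.49 ± 0.098 (adjusted p = 0.0132) in 17. The SE of the 21 line differences was larger, 0.22 for MtnC, 0.20 for MtnB and 0.11 for Ctr1B. The count on diet N ranged from 4 without line M092 or NC2 047 to 36 without NC2 005 and was 3 with the values as deposited, and without replicate 3 the difference of MtnC was -0.017 log2.

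On diet F, Seipin and Lsd-1, which encode lipid droplet proteins, were higher than on the mean of the other diets, as were Agpat2, an acyltransferase gene of glycerolipid synthesis, and the carboxylesterase genes alpha-Est8 and Est-Q. That mean includes diet C, where alpha-Est8, Est-Q and Seipin were lowest, so a fall on C raises the difference on F. CG15553 and Prx6b, a gene of the peroxiredoxin family that reduces peroxides, fell. In limma 14 genes differed on diet F, 12 higher and 2 lower, and 8 of them were also called on diet C, all 8 with the opposite sign.

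On diet F alpha-Est8 rose by 0.70 ± 0.14 log2 (moderated SE, adjusted p = 0.00968), in all 21 lines. Seipin (X, 2475956 to 2478301) rose by 0.62 ± 0.10 log2 (adjusted p = 0.000292) in 18 lines, with means of 12.14 on F, 11.20 on C, 11.72 on N and 11.65 on 4. CG17477 rose by 0.57 ± 0.10 log2 (adjusted p = 0.00294) in 18 lines. CG15553 (3R, 26924713 to 26926796) fell by 0.92 ± 0.14 log2 (adjusted p = 8.3e-05) in 20 lines, and Prx6b by 0.28 ± 0.061 (adjusted p = 0.0258) in 20. After their values were seen, Lsd-1 (0.45 ± 0.085 log2, adjusted p = 0.00406), Est-Q (0.65 ± 0.14, adjusted p = 0.0252), Agpat2 (0.31 ± 0.067, adjusted p = 0.0252) and PAPLA1, a phospholipase gene (0.27 ± 0.063, adjusted p = 0.0499), were singled out. Set against N and 4 alone, alpha-Est8 (N minus F -0.31 log2, 4 minus F -0.49) and Seipin (-0.42 and -0.50) did not pass (adjusted p = 0.9996 and 0.379, 0.359 and 0.0825), whereas CG15553 differed from both (1.17 each, adjusted p = 5.51e-05 and 5.56e-05). The mean of the fatty acid and triglyceride synthesis list rose by 0.11 log2 on diet F, in 16 lines, without passing the permutation test (adjusted p = 0.0962). The count on diet F was 34 without line M051, 9 without M077, 8 without NC2 038, 7 without NC2 084 and 0 with the values as deposited.

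Diet 4 had no gene of its own past the threshold: 0 genes differed from the mean of the other diets in limma, with 1131 at an unadjusted p under 0.05. Over the 4 diets together 243 genes differed, between 110 without line NC2 047 and 361 without M026. Between pairs of diets the counts were 393 for C and N, 94 for C and 4, 86 for C and F, 4 for N and 4, 7 for N and F, and 9 for 4 and F. The C and N count ranged from 187 without M073 to 681 without NC2 005, the C and 4 count from 2 without M052 to 189 without NC2 096, and the C and F count fell to 41 without NC2 084. The N and 4 count fell to 2 without M052 among others, the N and F count ranged from 4 without NC2 063 to 13 without NC2 005, and the 4 and F count from 2 without NC2 038 among others to 36 without M051.

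Lines differed far more than diets did. The highest F was that of Cyp6a14, a cytochrome P450 gene, and the 20 highest included LysP, which encodes a lysozyme, CHKov1, a gene of the choline kinase-like family with known natural variants, and Trx2, which encodes a thioredoxin. Among the lists, xenobiotic P450s differed more often than other genes, and genes of cytosolic ribosomal proteins, which make up the translation machinery, least often. In limma 10288 of 13202 genes (77.9%) differed between lines.

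Cyp6a14 had a line mean of 13.99 log2 in NC2 005 and 8.99 in NC2 038 (adjusted p = 4.31e-33). LysP ranged over 6.83 log2, from 12.58 in NC2 090 to 5.75 in NC2 047 (adjusted p = 4.56e-31). CHKov1 ranged over 5.82 log2 (adjusted p = 3.2e-30), and Trx2 over 5.13 (adjusted p = 1.52e-30), whose other transcript on the array correlated at only 0.339 over the arrays. The 20 genes with the highest F also included CG3397, mthl8 and Cp110, and CG32284 had the widest range among them, 7.68 log2. Background was not analysed, so the low end of such a range may be background, and its size is not an exact ratio of expression. The median gene ranged over 1.11 log2 between lines. As medians over genes, line took 48.7% of the variance of the cell means, diet 2.66% and the rest 47.8%. With neither line nor diet acting, the degrees of freedom would give line 24.1% and diet 3.61%. Since line took far more than that, 3.61% is too high a mark for diet, and 2.66% does not place diet below chance. Of the xenobiotic cytochrome P450 genes 44 of 45 differed between lines (Fisher's exact test, adjusted p = 0.0029), as did 27 of 28 glutathione transferases (0.0446), 20 of 20 carbohydrate-digesting enzymes (0.0446), 65 of 68 mitochondrial ribosomal proteins (0.0014) and 76 of 81 genes of oxidative phosphorylation (0.00208). By contrast 31 of 89 cytosolic ribosomal proteins differed (adjusted p = 8.11e-17), 9 of 18 muscle markers (0.0406) and 5 of 12 neuron markers (0.0403). Fisher's test takes genes as independent, and members of a list are correlated, so these p-values may be too small. Of 15 alternatives, these 8 lists passed in the same direction in 14 for P450s and for cytosolic ribosomal proteins, 12 for oxidative phosphorylation, 10 for glutathione transferases, 9 for mitochondrial ribosomal proteins and for muscle markers, 8 for neuron markers and 6 for carbohydrate-digesting enzymes. None passed without replicate 3, and mitochondrial ribosomal proteins differed less often than other genes with design 080306 alone (adjusted p = 0.00509) and without replicate 2 (1.85e-05), as did oxidative phosphorylation without replicate 2 (0.0097). Sequence differences of a line under a probe also change its signal, and these were not analysed here.

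Each array was matched to the lines by its pattern over the 200 genes with the highest F for line. These genes were chosen with the labels, so a match to the labelled line is partly built in. For 16 of 236 arrays the correlation was highest with the arrays of another line, and for 10 of these it exceeded that with the labelled line by 0.3 or more. These were the arrays labelled M027 (diet 4, replicate 2), M051 (diet 4, replicate 2), M073 (diet C, replicates 1 and 3, and diet N, replicate 2), M077 (diet 4, replicate 1), NC2 005 (diet N, replicate 3), NC2 081 (diet F, replicate 1) and NC2 096 (diet C, replicate 1, and diet 4, replicate 2). The array labelled M073 on diet C, replicate 1, matched line NC2 081, and the array labelled NC2 081 on diet F, replicate 1, matched M073. On the 500 most variable genes, chosen without labels, the median correlation with the own line was 0.467 over the other arrays. It was 0.753 for them on the 200 genes. All arrays were kept under their labels.

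**Figure D3:**
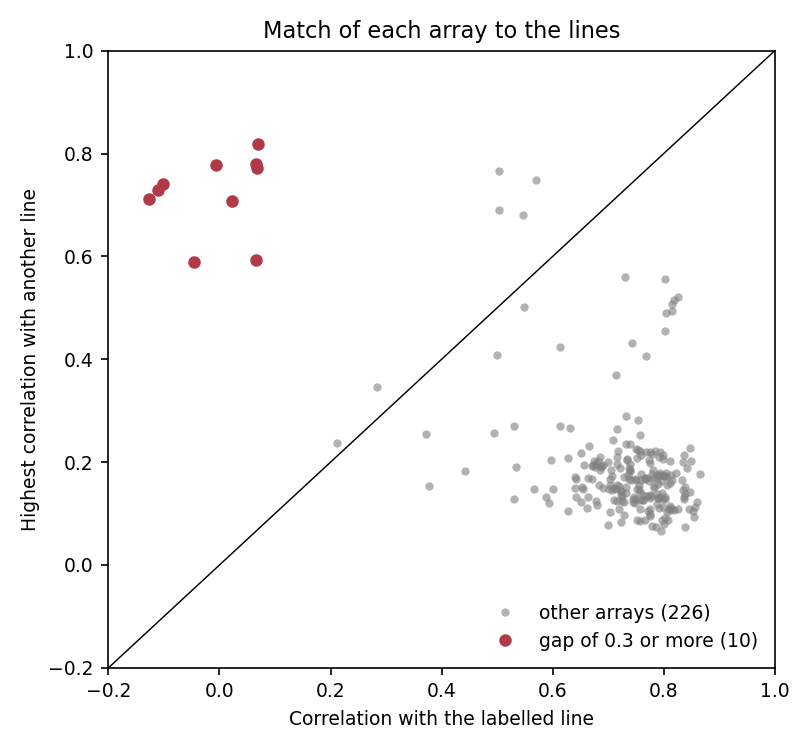
Correlation of each array with the arrays of its labelled line (horizontal axis) and the highest with another line (vertical axis), over the genes that differ most between lines, chosen with the labels. The 10 arrays marked lie between -0.127 and 0.0693 with their own line and between 0.589 and 0.82 with another.

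Few genes passed the test for a response to diet that differs between lines. CG32302, CG5084, CG9259 and Muc11A, a mucin gene, were the 4 genes past the threshold for a line-by-diet interaction, out of 13202, and 629 (4.76%) were at an unadjusted p under 0.05. CG32302 had F = 3.31 (adjusted p = 6.49e-05), CG5084 2.75 (0.00438), CG9259 2.58 (0.0139) and Muc11A 2.54 (0.0144). The deviations behind them lay in few cells. CG9259 deviated by -4.08 log2 from line plus diet in line M051 on diet C, CG32302 by -2.55 in line NC2 038 on diet N and by 1.91 in the same line on diet F, and Muc11A by -1.78 in M051 on diet C. Those cells held 1 pool (M051 on C, whose only array had a median correlation of 0.842 with the others, and NC2 038 on F) or 2 pools (NC2 038 on N). The count of 4 was 0 with the values as deposited and with median centring, 24 with no slide term, 1 with 1 array per pool, 16 with the replicate number as a block, 16 without the arrays matching another line, 8 without arrays of low correlation and 13, 27 and 34 without replicate 1, 2 and 3. Between the lines named M and those named NC2, 0 genes differed in limma, with 376 at an unadjusted p under 0.05.

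Diet F lowered survival and slowed development. On diet F larval survival was 0.633 ± 0.0965 (SD over 20 lines), against 0.81 ± 0.0883 on C, 0.817 ± 0.0743 on N and 0.808 ± 0.0835 on 4, and it was the lower value in 20 of 20 lines in each pair. Pupal survival was 0.669 ± 0.132 on F, against 0.923 ± 0.0397, 0.968 ± 0.0338 and 0.929 ± 0.0452 on C, N and 4. Both differed over diets with a permutation p of 1e-05, the smallest the shuffles can give (adjusted p = 2e-05). Development time, in the unit of the labels, which they do not name and whose values are all whole multiples of 3600, was 732060 on F, 702540 on 4, 676260 on C and 671580 on N (adjusted p = 2e-05), with SDs over lines of 53451, 49626, 39024 and 38799. Diets C and N differed by 4680 (permutation p = 0.542, adjusted p = 0.63). Weight was lowest on F, 0.961 ± 0.0967 against 1.01 ± 0.0889 on C (permutation p over diets 0.0136, adjusted p = 0.0164). Log triglycerides were -1.63 ± 0.32 on F and -1.95 ± 0.31 on 4 (permutation p over diets 0.00565, adjusted p = 0.00847, on ranks adjusted p = 0.0539), and log trehalose did not pass the test over the 4 diets (permutation adjusted p = 0.114), although C minus 4 was -0.52 (permutation p = 0.0245, adjusted p = 0.0491).

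**Figure D4:**
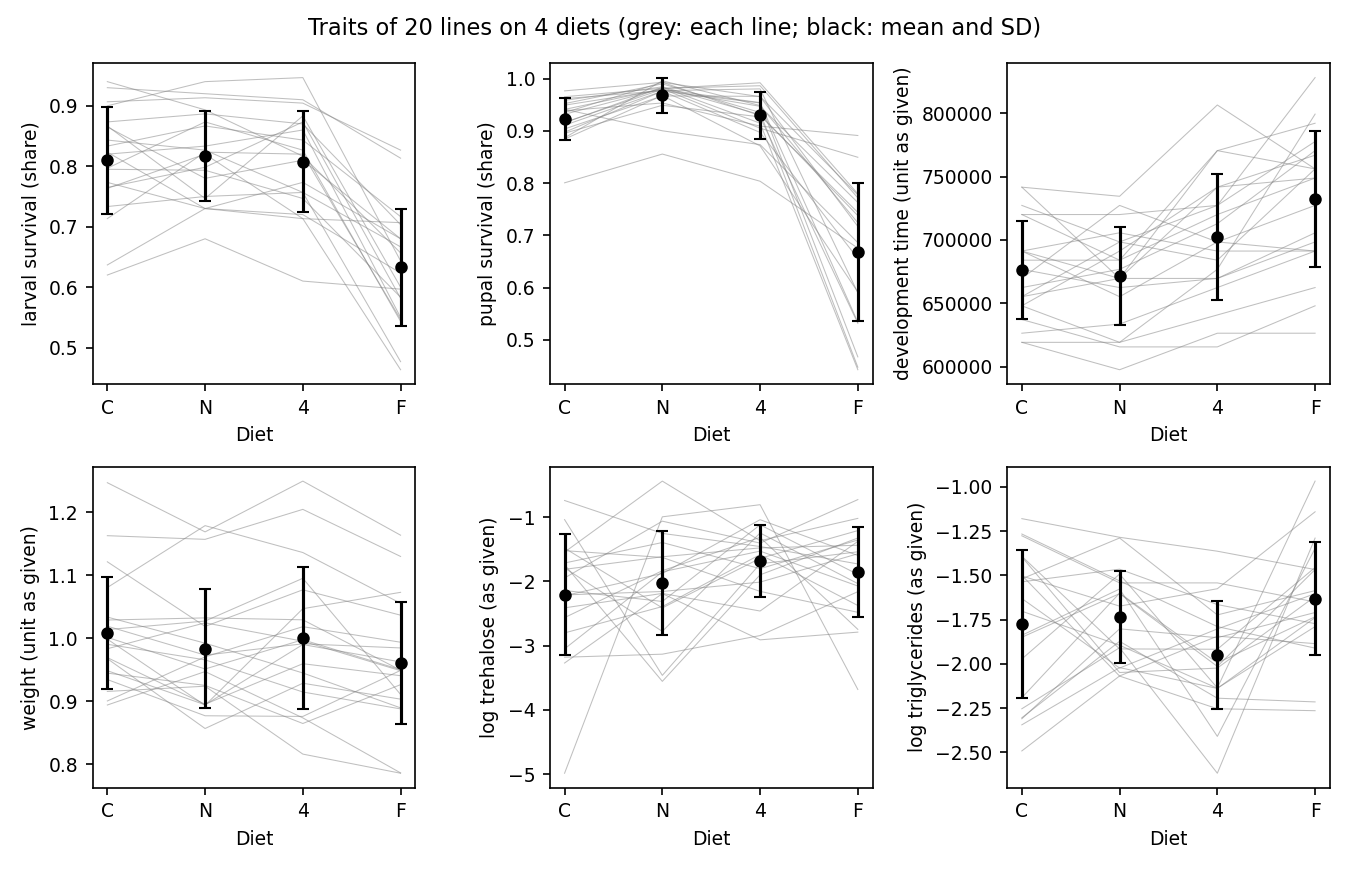
The 6 traits on each diet (horizontal axis), in the units of the labels, for 20 lines (grey lines) with mean and SD (black). Larval survival fell to 0.633 and pupal survival to 0.669 on diet F, while development time rose to 732060.

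All 6 traits differed between lines. The line term took 80.6% of the variance of weight, from 0.86 in NC2 096 to 1.21 in M026 (permutation adjusted p = 2e-05), and 56.9% of that of development time, from 617400 in NC2 063 to 759600 in M092 (2e-05). Larval survival (2e-05), pupal survival (0.0396), log trehalose (0.0449) and log triglycerides (0.00253) differed as well. Of 15 pairs of traits over 20 line means, 2 were related. Heavier lines had less trehalose, with r = -0.631 (permutation p = 0.00276, adjusted 0.0221) and rho = -0.753 (p = 0.00014, adjusted 0.0021), and r = -0.49 without the 2 lines farthest from the median weight. Heavier lines had more triglycerides, with r = 0.625 (permutation p = 0.00295, adjusted 0.0221) and rho = 0.642 (p = 0.00267, adjusted 0.02), and r = 0.538 without those lines.

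Lines that developed more slowly expressed less of NimC2, a gene of the Nimrod receptor family of blood cells, of CG8112, which belongs to the sterol O-acyltransferase family, and of CG11089. In limma 206 genes were tied to development time between the 20 lines, 49 rising with it and 157 falling. CG8112 fell by 0.44 ± 0.061 log2 per SD of development time (adjusted p = 0.00571), with r = -0.859 (permutation p = 1e-05, the smallest the draws can give, adjusted 2e-05), rho = -0.766 (permutation p = 0.00018) and r = -0.765 without the 2 lines farthest from the median. CG11089 fell by 0.27 ± 0.041 (adjusted p = 0.009) and NimC2 by 0.99 ± 0.15 (adjusted p = 0.009), and their r without those lines was -0.837 and -0.811. Without these 2 lines 7 genes passed, while the median slope of the 206 genes went from 0.30 to 0.32 log2 per SD and its median SE from 0.067 to 0.086. The count was 41 on ranks, 32 without arrays of low correlation, 461 without the arrays matching another line and 1436 with the values as deposited. CG8157 fell by 0.38 ± 0.06 log2 per SD of weight (adjusted p = 0.0451), the only gene for weight, and 0 genes passed on ranks, without the 2 farthest lines, with the values as deposited, with no slide term or without arrays of low correlation. For the other traits 0 genes passed in limma, with 1521 at an unadjusted p under 0.05 for larval survival, 137 for pupal survival, 1322 for trehalose, 656 for triglycerides and 327 for ai. After line and diet were taken out, 0 genes passed for any trait, with 1237, 907, 362, 181, 1301 and 470 at an unadjusted p under 0.05 for larval survival, pupal survival, development time, weight, trehalose and triglycerides.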

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

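In this part, the limit on genes chosen without labels, the runs without arrays matching another line and without low-correlation arrays, the array-quality test, the gap of 0.3 on those genes, the larval stage score, its comparison with other lists, the comparison of separate sets of slides, the array-weight shuffles and the readings given to the larval stage score and to the interaction fits were chosen after the results were seen.

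Among genes named in the report, 4 passed a test of whether the effect of diet differs between lines, although chance cannot be excluded for them (9 of 100 shuffles): CG32302 (adjusted p = 6.49e-05), CG5084 (0.00438), CG9259 (0.0139) and Muc11A (0.0144). For each, the largest deviation lay in line M051 on diet C, with 1 pool on an array at a median correlation of 0.842 with the others, or in line NC2 038 on diet N, with 2 pools.

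The 10 arrays that matched another line could be mislabelled, or swapped before hybridization. A first limit, a correlation of 0.5 or more with the other line and under 0.3 with the own line on the 500 most variable genes, was met by 4 of the 10, which by its own terms counts against a swap, but only 40.7% of the other arrays reach 0.5 with their own line there, so that limit could not decide. A gap of 0.3 on those genes, chosen after this, was met by 9 of the 10 and by 4 other arrays, which argues for a swap. Low quality (1 of 10 arrays with a median correlation under 0.9) and a leak from the next position on the slide (1 of 10) are argued against. In pools on several arrays the 3 pairs with such an array correlated at -0.122 to -0.00385 over the 200 genes with the highest F for line. The other pairs had a median of 0.871 over these genes, which are those that marked the 10 arrays. Over all genes the 3 pairs correlated at 0.892 to 0.939, and the other pairs at 0.758 to 0.996. No biological explanation was tested.

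The fall of lipid and sugar genes and the rise of Eig71Ea and dib on diet C could reflect more advanced larvae rather than the diet's direct effect. With the score of salivary glue genes as a covariate 14.1% of the genes stayed called, but their median size fell only from 0.38 to 0.29 log2 (75.4% left), 5 of 29 lists leave fewer calls as a covariate, and development time on C fell by 26280 against 4 (permutation adjusted p = 0.00226) and by 55800 against F (6e-05) but differed from N by 4680 (permutation p = 0.542), so the tests leave larval stage open. Mislabelled arrays are argued against, as 78.9% of the genes stayed called without them. Slides as the whole cause are argued against: of the 100 genes with the smallest p in 1 set of slides, 86.5% had the same sign in the other slides, with no pool in both sets, and 1 of 100 shuffles of diets gave as high a share (median 45.5%). A direct effect of diet C, the biological explanation, was not told apart from an earlier moult.

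Only 4 genes were called for an interaction although line and diet both act on expression. Too little precision is argued against for large effects only, since 83% of simulated genes with an interaction SD of 0.5 log2 were called. That size is large here, as the median gene had an SD over lines of 0.29 log2. Smaller interactions, and ones limited to few cells, were not simulated and remain open. Mislabelled arrays and poor arrays may hide some interaction: 16 genes were called without the arrays that match another line and 8 without arrays of low correlation, but leaving out a replicate number gave 13 to 34, so both remain open. With array weights 2852 genes were called, yet 9 of 10 shuffles of residuals gave over 1000 calls with such weights (355 to 7682), so that count arises with no interaction. Lines that respond alike to these diets, the biological explanation, remain possible, and of 100 shuffles of residuals, the real order included, 9 gave as many as 4 calls (highest other 12), so chance cannot be excluded for the 4 genes.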

How the results depend on the processing

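For the named genes the line effect and the signs of the diet differences held under most choices. These genes were picked on the same arrays, those for diets also by their sign over lines, so this is not independent support. The counts for diets moved, and the cause was not tested. The share of higher genes on diet C moved too: 168 of 427 in the main fit against 0 of 14 with the values as deposited. For named genes, 434 of 546 diet values kept sign and side of the threshold, 111 were weaker and 1 reversed (MtnC on diet N, -0.017 log2 without replicate 3 and up to 1.41 without replicate 2), and 749 of 753 line values, 29 of 60 interaction values and 18 of 24 trait values were the same. Counts are given in the order C, N, 4 and F, each against the other diets, where several diets are listed. With the values as deposited 14 genes differed on C (0 higher), 3 on N and 0 on F, 19 between C and N, 0 between C and 4, 6 between C and F, 0 between N and F and between 4 and F, and 14 over all diets, 5794 between lines, 0 by interaction, 1436 with development time and 0 with weight, and 14 list enrichments among line differences passed (8 in the report). With median centring the counts were 183 on C (56 higher), 7 on N, 128 over all diets, 141 for C and N, 21 for C and 4, 55 for C and F, 11 for N and F, and 0 by interaction. With no slide term they were 239 (50 higher), 7, 125, 176, 33, 52 and 11 in the same order, 24 by interaction, 0 for weight and 4 list enrichments, a number also given by the mean of all transcripts (4). With array weights they were 117 on C, 3 on N, 1 on 4, 7 on F, 80 over all diets, 90 for C and N, 24 for C and 4, 28 for C and F, 2 for N and 4, and 2852 by interaction. With 1 array per pool they were 5 on N, 220 for C and 4, 163 for C and F, 3 for 4 and F, and 1 by interaction, and with pools as replicates 39 on N, 5 on 4, 23 on F, 166 for C and 4, 2 for N and 4, 17 for N and F and 40 for 4 and F. Without dim genes 14 differed between 4 and F. With arrays of design 080306 alone 67 differed on C, 3 on F, 62 over all diets, 57 between C and N, 31 between C and 4, 15 between C and F, 2 between N and 4, 12 between N and F and 1 between 4 and F. With design 090901 alone 1 differed over all diets, 1 between 4 and F, 0 in each other diet comparison and 5976 between lines. The next 3 fits were chosen after seeing the data. With the larval stage score 61 differed on C, 6 on N, 23 on F, 60 over all diets, 24 between C and N, 6 between C and 4, 40 between C and F and 19 between 4 and F. Without the arrays matching another line 22 differed on N, 1 on 4, 9 on F, 185 between C and 4, 38 between C and F, 5 between 4 and F, 16 by interaction and 461 with development time. Without arrays of low correlation 3 differed on F, 153 over all diets, 36 between C and 4, 41 between C and F, 1 between N and 4, 4 between 4 and F, 8 by interaction, 32 with development time and 0 with weight. List calls were 36 at the preset correlation, 0 with an estimated correlation and 6 by permutation. The permutation test gave 3 with median centring, 0 with the values as deposited and 10 without arrays of low correlation. Development time gave 41 genes on ranks and 7 without the 2 farthest lines, and weight 0 in both, and the diet effect on triglycerides had adjusted p = 0.0539 on ranks. Without 1 replicate number at a time the counts ranged from 0 to 54 on C, 0 to 3 on N, 0 to 0 on 4, 1 to 5 on F, 1 to 17 over all diets, 0 to 140 for C and N, 0 to 0 for C and 4, 0 to 8 for C and F, 0 to 2 for N and 4, 1 to 2 for N and F, 0 to 1 for 4 and F, 13 to 34 by interaction, 6015 to 11701 between lines, 0 to 10 list enrichments and 0 to 0 for prefix. These fits hold fewer pools, and whether that or a difference tied to the replicate number moved the counts was not tested. Without 1 line at a time they ranged from 212 to 639 on C, 4 to 36 on N, 0 to 0 on 4, 7 to 34 on F, 110 to 361 over all diets, 187 to 681 for C and N, 2 to 189 for C and 4, 41 to 97 for C and F, 2 to 4 for N and 4, 4 to 13 for N and F, 2 to 36 for 4 and F and 9957 to 10366 between lines. Pools of 1 line on different diets had mean correlations of 0.0709, 0.112 and 0.0712 with the same replicate number (1, 2 and 3). With other numbers the means were -0.0406, -0.053 and -0.0465. Of the same-number pairs 46.5%, 55.4% and 46.8% were over 0.1, so a weak pairing within lines is not excluded. Blocking on the numbers used terms common to all lines, which cannot remove such a pairing. This block gave 16 interaction genes and changed no other count by over 1.5 times. Of 100 shuffles, the real order included, as many calls were given by 2 for all diets (243, highest other 737), 1 for C (427, 1), 3 for N (12, 1367), 3 for F (14, 862), 1 for C and N (393, 0), 1 for C and 4 (94, 1), 1 for C and F (86, 5), 2 for N and 4 (4, 183), 3 for N and F (7, 2645), 2 for 4 and F (9, 29), 1 for lines (10288, 644), 1 for development time (206, 19), 10 for weight (1, 966) and 11 for the lists (36, 45). Only the real order gave as many calls for C, C and N, C and 4, C and F, lines and development time, which argues against chance there. Chance cannot be excluded for weight and the lists. Nor can it be for all diets, N, F, N and 4, N and F, and 4 and F. There 2 or 3 of 100 orders gave as many calls, without adjustment over the comparisons. Shuffles with many times the real count may point to a structure of the samples, which was not tested. Signal over background was not analysed here, so dim genes are not told from background.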

Other observations

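In this part, the test of lists among genes tied to development time, the tests of slope size and of pairs of lines, and the metal gene list were chosen after the results were seen.

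Some genes that ecdysone switches on before pupariation were lower in lines that developed slowly. Of 19 genes of the ecdysone response 6 were tied to development time between lines, all with lower expression in slower lines (Fisher's exact test, adjusted p = 8.91e-06 over 29 lists). They were E23, which encodes a transporter that limits ecdysone action, ImpE2 and ImpE3, induced in imaginal discs, and the regulators Hr4, br and Eip78C. Of 21 salivary glue and late salivary genes 5 were tied to it (Fisher's exact test, adjusted p = 0.000212). These were Eig71Eg, Eig71Ei, Eig71Ef, Eig71Ec and Eig71Eh, all lower in slower lines. Fisher's test takes genes as independent. Members of these 2 lists had an estimated correlation of 0.17 and 0.19 in the diet fit, so both p-values may be too small. As all larvae were collected after the same 3 days on a diet, slow lines may have been sampled at an earlier point of the third instar. The 2 lines farthest from the median could set these slopes, and by a limit set beforehand on the share of genes still called they would, as 5 of the 206 genes stayed called without them. That limit alone could not decide: 32 of the 189 other pairs of lines left as few (median of the other pairs 83), and without these 2 lines the SD of development time over lines fell from 39194 to 32069, which leaves each slope less precise. The median slope of the 206 genes kept 105.4% of its size without the 2 lines (0.30 to 0.32 log2 per SD, median SE 0.067 to 0.086), all 206 with the same sign. Those of the 6 ecdysone and 5 salivary genes kept 108% and 79.1%. However, the 206 genes were chosen on all the lines, and leaving out any pair of lines kept 89.1 to 112% of their median slope. The size of the slopes therefore cannot decide either, and these 2 lines as the source remain open.

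Larvae on diet N could have met more metal ions, since MtnB and MtnC rose and the importer gene Ctr1B fell. The mean of the metallothionein genes that had not passed the test, MtnA and MtnD, was higher by 0.13 ± 0.091 log2 (SE over 21 lines, 13 lines higher, permutation p = 0.0926), which leaves this open. MtnA alone rose by 0.21 log2 in 15 lines (permutation p = 0.00183, adjusted 0.00412 over 9 genes), and MtnD by 0.04 (permutation p = 0.678, adjusted 0.75). ZnT35C, a zinc exporter gene, differed by 0.12 log2 (permutation p = 0.0588, adjusted 0.106), and Ctr1A, Ctr1C and MTF-1, the metal-responsive regulator, by -0.03, -0.03 and -0.04.

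The diet effects did not differ detectably between lines named M and NC2. Over the 4 diets 0 genes had a different diet effect in limma, with 334, 781, 1204 and 666 at an unadjusted p under 0.05 for C, N, 4 and F, which argues against a response that depends on the prefix at the sizes this number of lines can show.

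Arrays labelled M096, replicate 1, lay near line NC2 096. On diets 4, C and F (2 arrays) they correlated at 0.772, 0.779, 0.699 and 0.683 with NC2 096 and at 0.381, 0.436, 0.383 and 0.491 with the M096 arrays of other replicate numbers, and the array on diet N at 0.516 and 0.442. These values are over the genes with the highest F for line, which were chosen with the labels. On the most variable genes, chosen without labels, the values in the same order were 0.685, 0.758, 0.578, 0.502 and 0.387 with NC2 096. With M096 of other numbers they were 0.179, 0.328, 0.282, 0.288 and 0.348. A wrong label might explain this. By limits set beforehand, on the line genes, 0 of the 5 arrays met its terms (under 0.3 with M096 and 0.6 or more with NC2 096) and none met the terms against it, so it remains open.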
